A study of Mus musculus with 4 samples.

How the data were processed

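Poly(A)-selected RNA from the livers of 14-week-old male mice on a chow diet was sequenced in 4 libraries, 2 from DBA/2J and 2 from C57BL/6J mice. Both are inbred laboratory strains. Per the labels' protocols, libraries were made with Illumina poly(A)-capture reagents and run on a HiSeq instrument as single-end reads of 100 bases, with a stated depth of about 51 M reads per sample. The series' design text speaks of 2 mice per strain, so the libraries were taken as separate animals. Groups were taken from the strain label and replicate numbers from the sample titles.

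The deposited values were whole-number counts of reads per gene symbol, not normalised. Per the file headers, they were made with featureCounts 2.0.1 on the exons of Ensembl release 88 (GRCm38), summed by gene name; the submitters' processing notes name featureCounts 1.5.2 and STAR 2.4.0g1 with mm10/GRCm38. The header carries the paired-end option, whereas the labels state single-end reads. It carries no option for strand, for reads with several alignments or for reads overlapping several genes. Under that program's usual behaviour, such counts ignore strand, and reads that align to several places or overlap exons of several symbols go uncounted. Of 50584 symbols, 10403 had exons overlapping those of another symbol, and 7 lay on several chromosomes. No row lacked a gene name (0 rows). Reads of both strains were aligned to a reference derived from C57BL/6J, so a DBA/2J read that differs from it can be lost or placed elsewhere.

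Total counts were 48096706 and 52520737 for DBA/2J replicates 1 and 2, and 50300507 and 51172556 for C57BL/6J replicates 1 and 2. Albumin took 5.91% to 6.82% of counts. A count of 3, used as the floor for a gene at 0, corresponded to 0.0571 to 0.0624 CPM (counts scaled to library size) in a library. Floors and intervals on count ratios cover counting error only. Intervals on shares and medians over genes treat genes as independent and do not cover the spread between libraries. All mitochondrially encoded genes stood at 0 counts in each of the 4 libraries, so that gene list could not be tested.

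Counts were tested with edgeR 4.0.16 under R 4.3.3, by its quasi-likelihood F test (glmQLFit and glmQLFTest) with TMM scaling and strain as the sole term. The edgeR 4 form of the quasi-likelihood fit was used (legacy=FALSE); the installed version defaults to the older form, which was run as an alternative. Genes were kept by filterByExpr with its minimum count of 10, which left 15647. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p below 0.05. All log2 values are DBA/2J over C57BL/6J, and their standard errors were derived from the F statistic. CPM values used TMM-scaled library sizes. Counts were also simulated with the real means and library sizes (15304 genes tested). The DBA/2J against C57BL/6J fit recovered 18% of 50 genes changed by 0.5 on the log2 scale and 72% of 50 changed by 1. It recovered 100% of those changed by 2 or 3, and 2.68% of calls were false. Genes were drawn independently, with the same spread in both strains. In the real data the C57BL/6J pair differed more than the DBA/2J pair, so these rates need not hold there.

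A set of 39 gene lists (metabolic pathways, liver gene families, stress and immune responses, liver zones, cell types and genes with known strain alleles) was fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Of these lists, 38 had at least 3 tested members. They were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. In each list, members were also adjusted over the list alone. On simulated counts (15317 genes), a planted list of 30 genes shifted by 0.7 was found and 0 of 20 random lists were called. Genes were simulated independently, so this run does not test false calls for lists whose members vary together.

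Named genes were Mlycd, with its value in every library; the 10 largest positive and 10 largest negative log2 differences among called genes with a mean of at least 5 CPM, non-overlapping strains and a symbol that is not a predicted or clone name; up to 4 members of each list with the lowest adjusted p, and members needed to describe a count of 5 or fewer; tested strain-allele genes; tested genes starting within 500 kb of Mlycd; and Xist and Ddx3y. Results for some genes that meet this rule are not reported here. Further genes are marked where they were chosen after their values were seen.

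Whether called genes neighbour each other was tested by shuffling calls over tested genes 100000 times, one-sided. Gene types were taken from GENCODE release 21 for mouse (GRCm38), in which 47653 symbols of the files were matched. Coordinates are those of the files, in GRCm38. Annotated copies of ribosomal protein and oxidative phosphorylation genes were sought with blastn 2.17.0, by aligning coding sequences to all GENCODE transcripts. A copy needed an identity of at least 90% over at least 100 bases and at least 50% of the shorter sequence. A first version, which aligned whole transcripts without the coverage minimum, was discarded after its results were seen, because short repeats in untranslated regions matched unrelated genes. Total exon length of a symbol (log2 scale) and GC content of its longest transcript were fitted with smooth terms in mgcv 1.9.3. A first test of this step on a single simulated draw gave a residual of -0.102 and missed its limit; over 20 draws the mean residual was -0.0132, and a planted shift of -0.4 came out at -0.413.

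Alternatives were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma-voom (limma 3.58.1), the legacy quasi-likelihood fit, other count filters, each library left out in turn, a replicate block, an adjusted p below 0.01 and a test against a 1.5-fold change. Where a library was left out, the lone library of a strain was assumed to vary like the remaining pair. Calls from such fits change with the pair that sets the spread as well as with the library left out. They are not strain results in themselves. The genome sequence and reads were not used here.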

Results

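Liver mRNA was compared between DBA/2J and C57BL/6J mice, 2 inbred strains, with 2 libraries per strain from 14-week-old males. The counts assigned to genes ranged from 48096706 to 52520737 per library. Across genes, log2 CPM values correlated at r = 0.992 within DBA/2J, 0.982 within C57BL/6J and 0.945 to 0.954 between strains. The first principal component held 77.4% of the variance and separated the strains. The second held 15.9% and separated the C57BL/6J libraries from each other. The replicates of each strain differed by more than counting noise, with a chi-square per degree of freedom of 20.5 for DBA/2J and 84.7 for C57BL/6J. Xist had 17, 5, 4 and 5 counts and the Y-linked gene Ddx3y had 3332, 3867, 2763 and 2754, in the order DBA/2J replicates 1 and 2, C57BL/6J replicates 1 and 2. Ddx3y was higher in DBA/2J by 0.31 (edgeR adjusted p = 0.0415), a call lost without either DBA/2J library (adjusted p up to 0.29).

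The series concerns Mlycd, which encodes malonyl-CoA decarboxylase, the enzyme that converts malonyl-CoA to acetyl-CoA. Mlycd lies on chromosome 8 at 119394878 to 119411102 (GRCm38, forward strand). It had 2839 and 3412 counts in DBA/2J replicates 1 and 2, and 5302 and 5836 counts in C57BL/6J replicates 1 and 2. Its mean was 60.3 CPM ± 2.00 (SD, n = 2) in DBA/2J and 113 CPM ± 5.76 (SD, n = 2) in C57BL/6J. The difference, 1.87-fold lower in DBA/2J, was -0.91 ± 0.08 (SE) on the log2 scale, with an adjusted p of 0.0026 in edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted. The direction held when any library was left out. The call did not: without DBA/2J replicate 1 the log2 difference was -0.89 and without DBA/2J replicate 2 it was -0.94, neither past the threshold. In both fits the spread rests on the C57BL/6J pair, which differed more, so the lost call can reflect that spread. With each library left out in turn, the log2 difference ranged from -0.96 to -0.85.

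**Figure D1:**
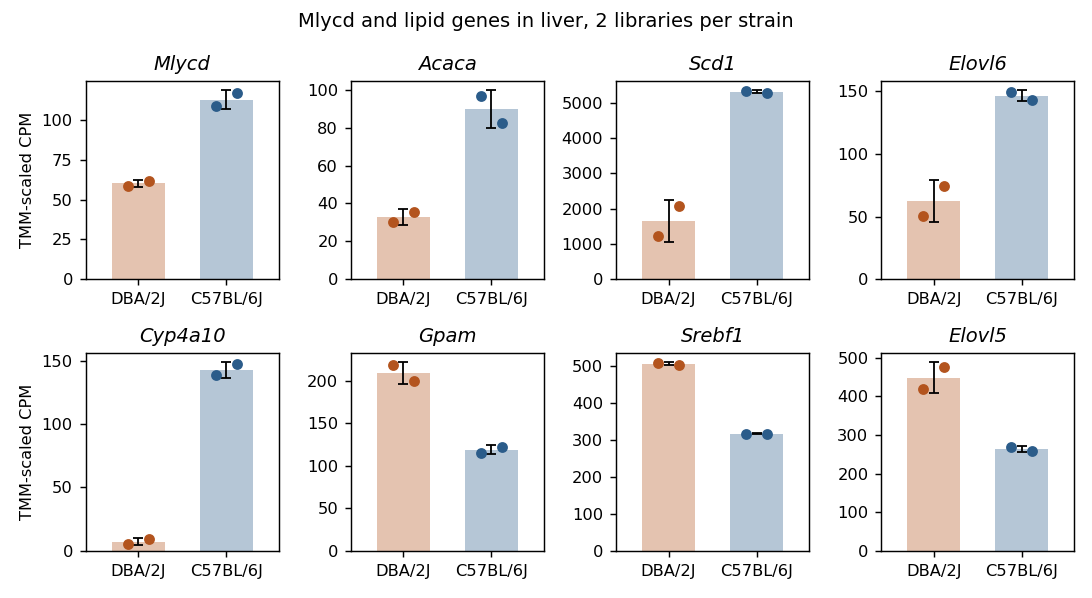
TMM-scaled CPM of Mlycd and 7 lipid genes, with a bar at the mean of each strain, error bars of 1 SD and a point per library (n = 2). Mlycd, Acaca, Scd1, Elovl6 and Cyp4a10 lie lower in both DBA/2J libraries, and Gpam, Srebf1 and Elovl5 higher.

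Of 10 other tested genes starting within 500 kb of Mlycd, 2 were called higher in DBA/2J and 0 lower by edgeR. Cotl1, an actin-binding protein gene, was higher by 0.67 ± 0.11 on the log2 scale (edgeR adjusted p = 0.016). Mbtps1, which encodes the site-1 protease that processes SREBP proteins, was higher by 0.33 ± 0.08 (edgeR adjusted p = 0.0482). Neither was called without DBA/2J replicate 1 or without DBA/2J replicate 2 (0 neighbours called in each; adjusted p up to 0.198 for Cotl1 and 0.306 for Mbtps1). Mbtps1 was also lost without C57BL/6J replicate 1 (0.0666), which left 1 neighbour called. Osgin1, the closest downstream gene, had a log2 value of -1.34 ± 0.47 and an edgeR adjusted p of 0.103, with 38284 counts in C57BL/6J replicate 1 and 14214 in replicate 2. Without C57BL/6J replicate 2 Osgin1 was called lower (-1.89, edgeR adjusted p = 2.09e-04), and 3 neighbours were then called. The log2 values of Hsbp1, Necab2, Hsdl1, Taf1c, Wfdc1, Tldc1 and Klhl36 were -0.21, -0.73, 0.17, 0.11, 0.48, 0.24 and 0.53, with edgeR adjusted p values from 0.0692 for Klhl36 to 0.718 for Taf1c.

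**Figure D2:**
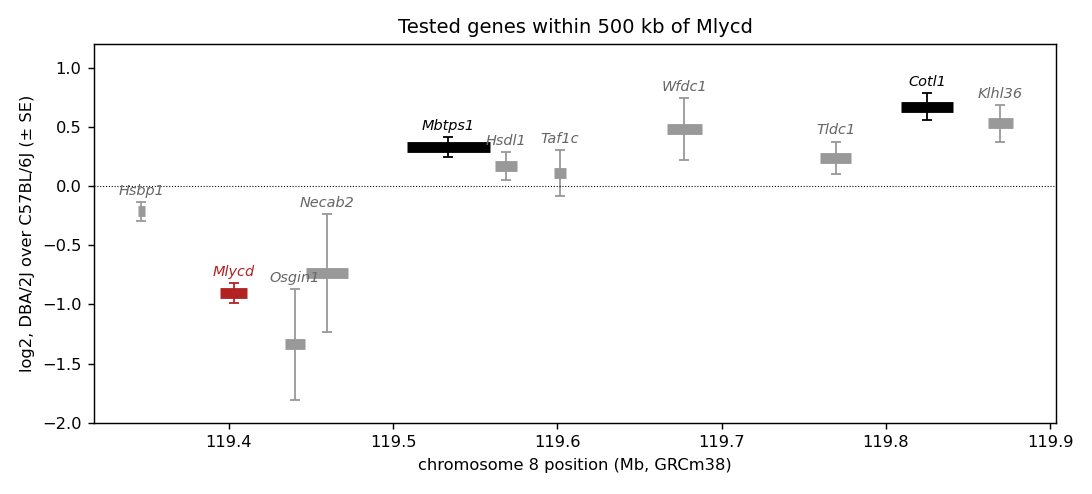
Log2 difference (DBA/2J over C57BL/6J, ± SE) of each tested gene within 500 kb of Mlycd, drawn as a bar over the gene's span in Mb on chromosome 8. Mlycd (red) lies at -0.91, while Mbtps1 and Cotl1 (black, called) lie above 0 and genes in grey were not called.

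Across the transcriptome, 2842 of 15647 tested genes (18.2%) differed between the strains in edgeR's quasi-likelihood test: 1454 were higher and 1388 lower in DBA/2J. At least 2-fold differences were found in 745 of the higher and 466 of the lower genes. The strains' libraries did not overlap for 63.8% of tested genes, where chance gives 33.3%. The number of calls depended on the libraries: it was 292 without DBA/2J replicate 1, 313 without DBA/2J replicate 2, 3926 without C57BL/6J replicate 1 and 4904 without C57BL/6J replicate 2. Fits without a DBA/2J library take their spread from the C57BL/6J pair, which differed more. Those without a C57BL/6J library take it from the DBA/2J pair. Scaling by library totals alone gave 1924 higher and 1024 lower genes.

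**Figure D3:**
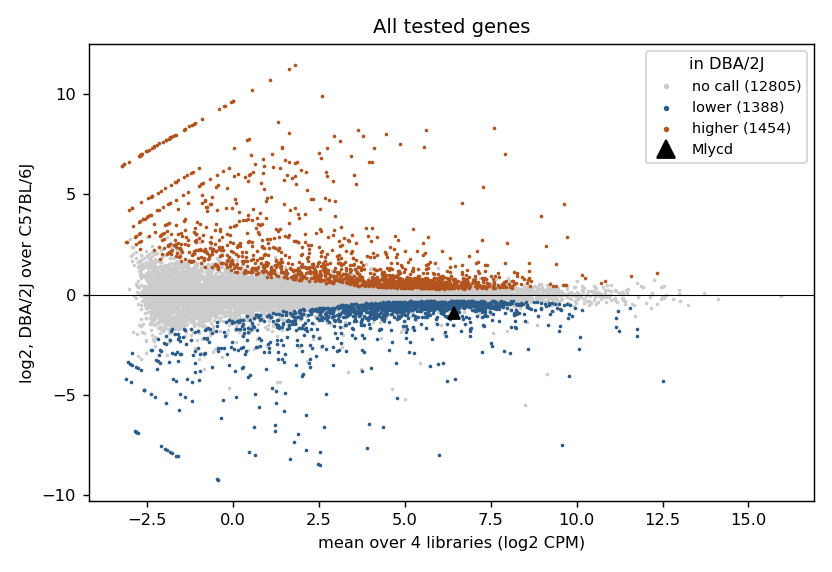
Log2 difference (DBA/2J over C57BL/6J) against mean log2 CPM over the 4 libraries for each tested gene, coloured by call. The plot holds 1454 genes called higher and 1388 called lower, with Mlycd marked by a triangle.

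Among the 10 largest increases in DBA/2J, Tmc5 had 548 and 699 counts in DBA/2J against 0 and 1 in C57BL/6J, a ratio of 1188 with a 95% counting interval from 213 to 46953. Serpina3c, a serine protease inhibitor gene, was higher by 8.32 ± 0.27 on the log2 scale. C1s2, Mrap2, Corin and Ntrk2 followed with 8.04, 7.91, 7.90 and 7.38. Corin encodes the protease that activates atrial natriuretic peptide, and Ntrk2 the receptor of brain-derived neurotrophic factor. Eno1b, Nuggc, Obp2a and Ctse differed by 7.32, 7.08, 7.02 and 6.60. These calls, with edgeR adjusted p values from 1.36e-04 to 0.00162, held when any single library was left out. Serpina3c belongs to a family of near-identical copies that can share reads, and Eno1b, a retrotransposed enolase gene, is 99.8% identical to the processed copy Gm4735, which stood at 6.81.

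The largest decreases in DBA/2J were in Mup15 (0.505 CPM against 127 CPM), the alpha-globin copy Hba-a2 (-7.83 ± 0.36 on the log2 scale), the zinc finger gene Zfp970 (-7.64 ± 0.68) and Mup11 (-7.48 ± 0.22). Nlrp12, an innate immune receptor gene, stood at -6.59, and the cytochrome P450 genes Cyp2c69 and Cyp2c40 at -6.58 and -6.44. Hdc, which encodes histidine decarboxylase, stood at -4.94, the antitrypsin copy Serpina1e at -4.30 and the fatty acid omega-hydroxylase Cyp4a10 at -4.29. Serpina1e fell from a mean of 11046 CPM in C57BL/6J to 560.3 CPM in DBA/2J. The edgeR adjusted p values ran from 1.36e-04 to 0.00306. The Zfp970 call was lost without either DBA/2J library (adjusted p up to 0.0556), and the other 9 held with any single library left out. Reads of Mup, Cyp2c, Cyp4a, Serpina1 and alpha-globin genes can be shared between copies. Hba-a2 had 4 and 1 counts in DBA/2J against 583 and 561 in C57BL/6J, while the copy Hba-a1 was called higher in DBA/2J. Reads placed at the other copy can therefore not be told apart from a lower Hba-a2 mRNA level.

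Lipid genes moved in both directions. Of 18 fatty acid synthesis genes, 3 were higher and 5 lower in DBA/2J (9, 4 higher and 5 lower, when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.464). Lower were Acaca, which encodes the acetyl-CoA carboxylase that makes malonyl-CoA (-1.45 ± 0.13, edgeR adjusted p = 0.0024), the desaturase gene Scd1 (-1.69), Elovl6 (-1.23), Me1 (-1.11) and Thrsp (-0.80). Higher were Gpam (0.81), the lipogenic transcription factor gene Srebf1 (0.68) and Elovl5 (0.76). Acaca kept its call when any library was left out. The calls of Scd1, Thrsp, Gpam, Srebf1 and Elovl5 were lost without either DBA/2J library (edgeR adjusted p up to 0.082 for Gpam and 0.279 for Thrsp), and those of Me1 and Elovl6 without DBA/2J replicate 1 (edgeR adjusted p = 0.071 and 0.0501). The list then held 0 higher and 1 lower gene, and 0 higher and 3 lower without DBA/2J replicate 2.

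Of 25 PPARalpha target and peroxisomal oxidation genes, 6 were lower and 1 higher (11, 2 higher and 9 lower, when adjusted over the list alone). The list was lower by camera at an adjusted p of 2.64e-04, with a median log2 of -0.35. This call was lost in camera with an estimated correlation (adjusted p = 0.962, unadjusted p = 0.147). There the adjustment gave every tested list the same value of 0.962. The number of lower genes was 3 without DBA/2J replicate 1, 3 without DBA/2J replicate 2, 13 without C57BL/6J replicate 1 and 10 without C57BL/6J replicate 2. Cyp4a10 and Cyp4a31 were lower (-4.29 and -3.22), whereas Cyp4a32 was higher (1.65); these Cyp4a copies can share reads. Mitochondrial fatty acid oxidation genes were called in 3 of 22 cases, Etfb (-0.85), Eci1 (-0.54) and Eci2 (-0.51), each lower (3 when adjusted over the list alone; camera adjusted p = 0.461). These 3 calls were lost without either DBA/2J library (edgeR adjusted p up to 0.144), 6 genes were lower without C57BL/6J replicate 1, and 2 were higher without C57BL/6J replicate 2. Of 4 ketone body synthesis genes, Bdh1 was called, higher by 0.39 (2 called when adjusted over the list alone; camera adjusted p = 0.565). Bdh1 lost its call without either DBA/2J library and without C57BL/6J replicate 1 (0.0534; highest edgeR adjusted p = 0.304), and 2 ketone body genes were higher without C57BL/6J replicate 2. That fit also gave 2 higher PPARalpha targets.

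Most genes of the ribosome and many of the respiratory chain were lower in DBA/2J. Of 80 cytoplasmic ribosomal protein genes, 69 were lower and 0 higher (78 called when adjusted over the list alone), with a median log2 of -0.56 and a camera adjusted p of 2.8e-26 (adjusted p = 0.962 with an estimated correlation). Rpl29 was lower by -3.53 ± 0.11, Rplp0 by -1.61 ± 0.09, Rpsa by -1.60 ± 0.10 and Rps18 by -1.57 ± 0.10, and these 4 calls held with any library left out. Of 75 nuclear-encoded oxidative phosphorylation genes, 43 were lower and 0 higher (52 when adjusted over the list alone), with a median of -0.41 and a camera adjusted p of 7.61e-11 (adjusted p = 0.962 with an estimated correlation). Cox7a2l stood at -1.13, Atp5h at -0.76, Ndufa5 at -0.73 and Uqcrb at -0.64; the last 3 calls were lost without either DBA/2J library (edgeR adjusted p up to 0.116). Without DBA/2J replicate 1 the calls fell to 4 ribosomal protein and 1 oxidative phosphorylation gene, and without DBA/2J replicate 2 also to 4 and 1, while the 2 list calls held at a camera adjusted p of 1.4e-23 and 1.62e-10, and of 1.09e-21 and 6.15e-09. There was 1 higher oxidative phosphorylation gene without C57BL/6J replicate 2. Ribosomal protein genes have many near-identical copies in the genome, with a median of 10 annotated copies per gene, and reads that match several places were not counted. Genes of short total exon length were lower more widely. Members of the 2 lists had a median exon length of 1659 bases against 4143 in other genes. Log2 values of other genes rose with exon length (Spearman rho = 0.252), and 4940 other genes of like length had a median log2 of -0.12. Exon length here covers all annotated exons of a symbol and can exceed that of any single transcript.

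Part of the stress and immediate early genes tested were lower in DBA/2J. Of 22 endoplasmic reticulum stress and heat shock genes, 12 were lower and 0 higher (20, 2 higher and 18 lower, when adjusted over the list alone; camera adjusted p = 2.22e-08, and adjusted p = 0.962 with an estimated correlation). The chaperone gene Hspa8 stood at -1.56 ± 0.14, and the secretory pathway genes Creld2, Manf and Sdf2l1 at -1.81, -1.35 and -0.64. Of 15 immediate early genes, 4 were lower and 0 higher (7 when adjusted over the list alone; camera adjusted p = 1.36e-04, and adjusted p = 0.962 with an estimated correlation). These were Jun (-1.12), Btg2 (-2.85), Egr1 (-2.07) and Zfp36 (-0.50). The immediate early list was fixed as a technical check. The labels give no batch, so a difference in how the animals were handled cannot be told apart from strain. Hspa8, Creld2, Manf and Jun kept their calls with any library left out, and Sdf2l1, Btg2, Egr1 and Zfp36 lost them without either DBA/2J library (edgeR adjusted p up to 0.281 for Zfp36). In both lists fewer genes were called lower without either DBA/2J library. More were called lower without either C57BL/6J library, most of all without replicate 2, where a stress gene was also called higher.

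The acute phase list was lower by camera (adjusted p = 0.00835, and adjusted p = 0.962 with an estimated correlation), but the call depended on single libraries. Of its 26 genes, 3 were lower and 2 higher (12, 2 higher and 10 lower, when adjusted over the list alone): Hamp (-2.40) and Orm1 (-0.94) were among the lower, and Hamp2 (4.59) and Apcs (196 CPM against 91.2 CPM) were higher. These 4 calls were lost without either DBA/2J library (edgeR adjusted p up to 0.185 for Orm1), which left 0 genes called in each case. Lower genes numbered 6 without C57BL/6J replicate 1 and 19 without C57BL/6J replicate 2. C57BL/6J replicate 1 stood apart in genes picked after their values were seen. Saa1 had 95929 counts in it, against 6897 in C57BL/6J replicate 2 and 4792 and 1988 in DBA/2J. Lcn2 had 4488 counts in it, against 175, 116 and 74. The neutrophil marker S100a9 had 133 counts in it, against 7, 10 and 7. The list's camera adjusted p was 0.806 without C57BL/6J replicate 1 and 0.0706 without DBA/2J replicate 2.

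Most of the large multigene families had called genes in both directions, with reads that can be shared between copies. Carboxylesterases had calls in 1 direction only, with 11.8% of genes called against 18.2% of all tested genes. Of 21 major urinary protein genes, 11 were lower and 4 higher (16, 5 higher and 11 lower, when adjusted over the list alone; camera adjusted p = 2.37e-08, and adjusted p = 0.962 with an estimated correlation). Mup11, Mup12 and Mup14 stood at -7.48, -3.44 and -4.05. With gene clusters counted once the camera adjusted p of this list was 0.215, that of the acute phase list 0.0511 and that of the H2 list, then called lower, 0.0171. Without DBA/2J replicate 1 there were 6 lower and 1 higher Mup genes, and without DBA/2J replicate 2 there were 5 and 1. Of 23 clade A serpin genes, 7 were higher and 4 lower (11 when adjusted over the list alone; camera adjusted p = 0.00113, and adjusted p = 0.962 with an estimated correlation). Serpina3e-ps had 337 and 292 counts in DBA/2J against 0 and 2 in C57BL/6J, a ratio of 299.6 with a 95% counting interval from 82.6 to 2479, and Serpina5 stood at 7.11 CPM against 0.508 CPM. The serpin list was not called without C57BL/6J replicate 2 (camera adjusted p = 0.115), and 12 serpin genes were higher without C57BL/6J replicate 1. Lower serpin genes numbered 1 without DBA/2J replicate 1, 1 without DBA/2J replicate 2 and 6 without C57BL/6J replicate 2. Of 49 cytochrome P450 genes of families 1 to 3, 10 were higher and 9 lower (24, 13 higher and 11 lower, when adjusted over the list alone; camera adjusted p = 0.928), among them Cyp2c44 (-2.90), Cyp3a13 (-2.07) and Cyp2c39 (3.24). Of 47 conjugating enzyme genes, 8 were higher and 9 lower (22, 12 higher and 10 lower, when adjusted over the list alone; camera adjusted p = 0.928), among them Ugt1a10 (3.25) and Ugt1a9 (2.73), which share exons, Mgst3 (1.31) and Ugt2b38 (-2.18). Of 17 carboxylesterase genes, Ces1b (1.57) and Ces1e (0.57) were higher and 0 lower (2 when adjusted over the list alone; camera adjusted p = 0.938). Of 26 H2 genes, 6 were higher and 5 lower (12, 7 higher and 5 lower, when adjusted over the list alone; camera adjusted p = 0.761), with H2-K1 at -2.12, H2-Q7 at -2.91 and H2-T22 at -1.11, and the H2 list was called lower without C57BL/6J replicate 2 (camera adjusted p = 0.0104). Without DBA/2J replicate 1 the calls fell to 8 P450 genes (3 higher and 5 lower), 4 conjugating enzyme, 1 carboxylesterase and 4 H2 genes, and without DBA/2J replicate 2 to 7 (3 and 4), 3, 1 and 4. There were 4 lower carboxylesterase genes, 14 lower conjugating enzyme genes, and 10 higher and 5 lower H2 genes without C57BL/6J replicate 1. Leaving out C57BL/6J replicate 2 gave 6 higher and 10 lower H2 genes and 16 higher P450 genes. Ces1e lost its call without either DBA/2J library (edgeR adjusted p up to 0.141), and Mgst3 without DBA/2J replicate 2 (edgeR adjusted p = 0.0567).

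**Figure D4:**
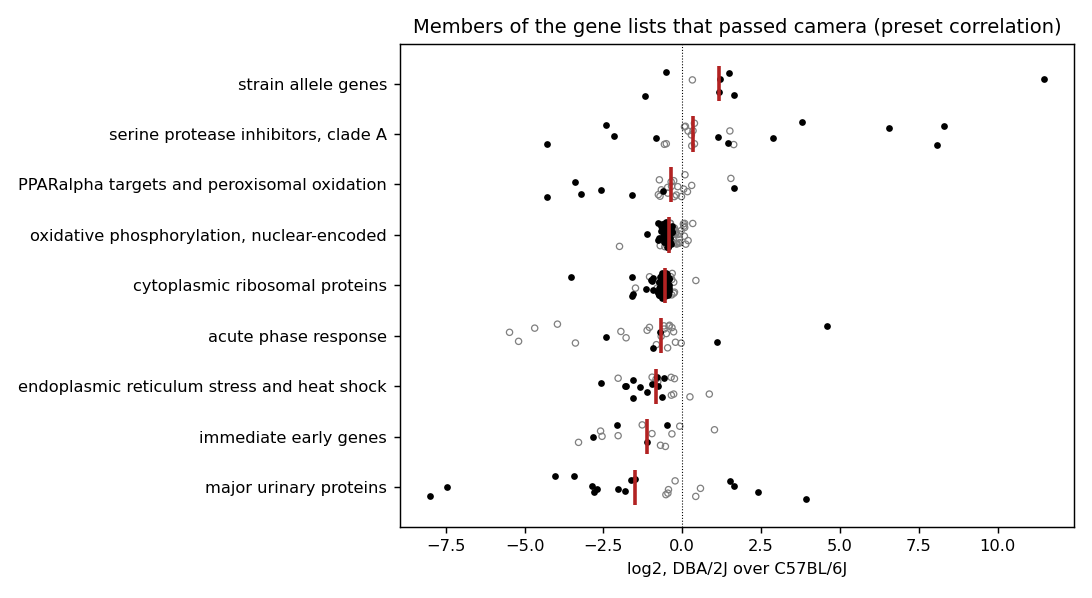
Log2 difference (DBA/2J over C57BL/6J) of each member of the 9 lists that passed camera at the preset correlation, 1 list per line, with called genes filled, others open and a red line at the list's median. The medians of ribosomal protein and oxidative phosphorylation genes lie at -0.56 and -0.41.

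Genes with known strain alleles were fixed as a list, and 8 were tested, of which 5 were higher and 2 lower (7 when adjusted over the list alone). The camera adjusted p was 1.36e-04, and 0.962 with an estimated correlation. The genes were chosen because alleles were known to differ, so this call is a check and not a finding. C57BL/6J mice carry a deletion in Nnt, which was higher in DBA/2J by 1.49 ± 0.09. DBA/2J mice lack functional complement component encoded by Hc, whose mRNA was lower by -1.17 ± 0.13. Alad and Glo1, which have extra copies in DBA/2J, were higher by 1.16 ± 0.09 and 1.19 ± 0.09. H2-Ea-ps had 362 and 360 counts in DBA/2J and 0 in both C57BL/6J libraries, at least 229-fold higher against a floor of 3 counts over the group. Dhtkd1 was higher by 1.65 ± 0.21, and Myo5a had a log2 value of 0.32 (edgeR adjusted p = 0.514). The calls of Hc and Dhtkd1 were lost without either DBA/2J library (highest edgeR adjusted p of 0.0902 and 0.0895), and 4 higher and 0 lower genes of the list were left in each case.

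None of the other 5 metabolic lists passed camera with all 4 libraries. Of 24 cholesterol synthesis genes, 1 was higher (Dhcr7, 0.51) and 4 lower, among them Sqle (-0.58), Hmgcs1 (-0.45) and Ebp (-0.34) (5 when adjusted over the list alone; camera adjusted p = 0.659). Of 21 bile acid genes, Abcg8 (0.62) and Slco1a1 (0.42) were higher and Slco1a4 (-1.61) and Abcg5 (-0.44) lower (4 when adjusted over the list alone; camera adjusted p = 0.664). Of 28 lysine and branched-chain amino acid breakdown genes, Bckdhb (0.74) and Dhtkd1 were higher and Mcee (-0.75) and Gcdh (-0.56) lower (4 when adjusted over the list alone; camera adjusted p = 0.643). Of 36 urea cycle and other amino acid genes, Ftcd (0.50) was higher and Amdhd1 (-0.47) lower (0 when adjusted over the list alone; camera adjusted p = 0.664). Of 17 gluconeogenesis and glucose genes, 2 were higher, among them Ppargc1a (0.91), and 3 lower, among them Igfbp1 (-3.42) and Pygl (-0.44) (5 when adjusted over the list alone; camera adjusted p = 0.444). Of these named calls, those of Slco1a4 and Igfbp1 held with any library left out. The others were lost without either DBA/2J library (edgeR adjusted p up to 0.102 for Bckdhb and 0.289 for Slco1a1), and Slco1a1 also without C57BL/6J replicate 2 (0.0505) and Ftcd without C57BL/6J replicate 1 (0.0523). Both fits without a C57BL/6J library take their spread from the DBA/2J pair alone, which differed less. Their calls therefore also reflect that smaller spread and do not by themselves show dependence on a library. The glucose list was called lower by camera without C57BL/6J replicate 1, and the urea cycle list higher without C57BL/6J replicate 2. In that fit 9 lysine and branched-chain, 5 bile acid and 3 cholesterol genes were higher. With C57BL/6J replicate 1 left out, 6 glucose genes were lower, and 2 urea cycle genes were higher and 4 lower. Without either DBA/2J library 1 bile acid gene and 1 glucose gene stayed called, both lower, and 0 genes of the other 3 lists.

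Regulatory and zonal lists likewise did not pass camera. Interferon-stimulated genes had 1 higher, Xaf1 (1.65), and 3 lower, Gbp3 (-1.25), Bst2 (-0.43) and Trim30a (-0.80), of 43 (4 when adjusted over the list alone; camera adjusted p = 0.219). Complement and coagulation genes had 2 higher, Masp1 (1.13) and F11 (0.79), and 4 lower, among them C8g (-0.62), of 35 (6 when adjusted over the list alone; camera adjusted p = 0.817). NRF2 targets had 2 higher and 4 lower of 18, among them Gstm3 (1.17) and Gclm (-0.58) (7, 2 higher and 5 lower, when adjusted over the list alone; camera adjusted p = 0.444). Clock genes had 2 higher, Clock (0.54) and Arntl (0.93), and 1 lower, Bhlhe40 (-1.02), of 20 (3 when adjusted over the list alone; camera adjusted p = 0.924). Male-biased liver genes had 3 higher and 3 lower of 18, among them Cspg5 (2.24) and Mup20 (-1.83) (7, 4 higher and 3 lower, when adjusted over the list alone; camera adjusted p = 0.833). Female-biased liver genes had 3 higher and 2 lower of 15, among them Cyp3a41a (5.98) and Rtn4 (-1.54) (9, 5 higher and 4 lower, when adjusted over the list alone; camera adjusted p = 0.823). Pericentral genes had 1 higher, Cyp2c29 (0.70), and 3 lower, Cyp2c50 (-1.49), Glul (-0.46) and Oat (-0.96), of 18 (5, 1 higher and 4 lower, when adjusted over the list alone; camera adjusted p = 0.387). Periportal genes had 1 higher, Etnppl (1.08), and 1 lower, Ctsc (-0.78), of 17 (1, 1 higher and 0 lower, when adjusted over the list alone; camera adjusted p = 0.659). Cell cycle genes had 3 lower, Ccnd1 (-2.01), Rrm2 (-2.49) and Mcm6 (-1.64), and 0 higher of 22 (3 when adjusted over the list alone; camera adjusted p = 0.111). The calls of Cyp3a41a, Rtn4 and Ccnd1 held with any library left out; Cspg5 and Cyp2c50 were lost without DBA/2J replicate 2, and the other genes named here without either DBA/2J library (edgeR adjusted p up to 0.0817 for Masp1 and 0.266 for Arntl). Without DBA/2J replicate 1 camera called interferon-stimulated (adjusted p = 0.00377), pericentral (0.0235) and cell cycle genes (0.00965). Interferon-stimulated genes were also called without C57BL/6J replicate 2 (0.0487) and with no low-count filter (0.0424), cell cycle genes against a 1.5-fold change (0.0356), and male-biased genes without C57BL/6J replicate 1 (0.019). Lower genes without C57BL/6J replicate 2 numbered 15 for interferon, 7 for complement, 8 for NRF2, 3 for clock and 4 for female-biased genes. Higher genes in that fit numbered 2, 5, 2, 7 and 5 in the same order, 5 for male-biased and 6 for periportal genes. Without C57BL/6J replicate 1, higher genes numbered 2 for interferon, and lower genes 5 for interferon, 4 for clock, 5 for pericentral and 2 for periportal genes. Without DBA/2J replicate 1 the male-biased, female-biased, pericentral and cell cycle lists had 3, 2, 1 and 1 called genes, without DBA/2J replicate 2 they had 2, 2, 0 and 1, and the other 5 lists had 0 in both fits. Reads of Mup, Cyp2c, Cyp3a and Gst genes can be shared between copies. Median and mean log2 differed in sign for clock, male-biased, female-biased, H2, conjugating enzyme, cholangiocyte and erythroid genes, and for carboxylesterases camera pointed up while both lay below 0.

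None of the 8 lists of other cell types passed camera with all libraries, edgeR and the preset correlation. Of 17 macrophage markers, Slc40a1 (0.94) was higher and Marco (-2.97) and Folr2 (-2.13) lower (3 when adjusted over the list alone; camera adjusted p = 0.817). Of 16 sinusoidal endothelial markers, Stab2 (0.40) was higher and Lyve1 (-1.16) lower (1, 0 higher and 1 lower, when adjusted over the list alone; camera adjusted p = 0.721). Of 15 stellate cell markers, Reln (1.30) was higher (1 when adjusted over the list alone; camera adjusted p = 0.073). Of 12 cholangiocyte markers, Spp1 (-1.86) was lower (1 when adjusted over the list alone; camera adjusted p = 0.742). Of 10 lymphocyte markers, Cd4 (1.89) was higher and Gzmb, with 0 and 1 counts against 29 and 11 (ratio 42.0 with a 95% counting interval from 7.12 to 1699.6), lower (2 when adjusted over the list alone; camera adjusted p = 0.659). Of 4 neutrophil markers tested, 0 were called by edgeR (0 when adjusted over the list alone; camera adjusted p = 0.468). Of 7 erythroid markers, Alas2 (0.93) and Hba-a1 (0.72) were higher and Hba-a2 (-7.83) lower (3 when adjusted over the list alone; camera adjusted p = 0.664). Of 5 adipose, pancreas and muscle markers, Cela1 (1.47) was higher, and Cela2a had 0 counts in both DBA/2J libraries against 30 and 33, at least 22.0-fold lower (2 when adjusted over the list alone; camera adjusted p = 0.823). Reads of Hba-a1 and Hba-a2 can be shared between these copies. Slc40a1, Hba-a2 and Cela1 kept their calls with any library left out. The other genes named here that were called lost them without either DBA/2J library (edgeR adjusted p up to 0.0731 for Reln and 0.284 for Stab2), and Gzmb had too few counts to be tested without C57BL/6J replicate 1. Camera called the stellate list higher without DBA/2J replicate 1 (adjusted p = 0.00298) and without C57BL/6J replicate 1 (1.45e-04), and with all 4 libraries under limma-voom (0.0334) and with no low-count filter (0.0127). It called the neutrophil list lower without C57BL/6J replicate 2 (1.51e-04) and against a 1.5-fold change (0.048), with 4 genes lower in the former. Without C57BL/6J replicate 1, higher genes numbered 10 for stellate, 3 for macrophage, 2 for sinusoidal and 1 for cholangiocyte markers, and 0 lymphocyte markers were lower. Without C57BL/6J replicate 2, lower genes numbered 7 for macrophage, 3 for lymphocyte, 2 for sinusoidal and 2 for cholangiocyte markers. Without either DBA/2J library 1 macrophage marker (higher), 1 erythroid marker (lower) and 1 adipose, pancreas and muscle marker (higher) stayed called, and 0 genes of the other 5 lists.

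Called genes lay next to each other along the chromosomes more often than shuffled calls. There were 674 pairs of neighbouring tested genes that were both called, against a mean of 515.5 in shuffles, a ratio of 1.31 (one-sided permutation p = 1e-05, the smallest that 100000 shuffles can give). Both genes of a pair differed in the same direction in 64.2% of these pairs, more than with signs shuffled (permutation p = 5e-05, the smallest that 20000 shuffles can give). The ratio was 5.38 without DBA/2J replicate 1, 4.49 without DBA/2J replicate 2 (where the p for direction was 0.0571) and 1.09 without C57BL/6J replicate 2, and without C57BL/6J replicate 1 there were 1137 pairs against a mean of 947 in shuffles. Of the called genes, 48.8% were lower in DBA/2J (exact 95% interval 47.0% to 50.7%), against 34.7% with scaling by library totals, 36.3% without DBA/2J replicate 1 and 36.4% without DBA/2J replicate 2. The share rose with expression: with tested genes split by mean CPM into 3 groups of equal size, it was 31.7% in the lowest, 49.7% in the middle and 721 of 1264 in the highest group (exact 95% interval 54.3% to 59.8%). Both intervals treat genes as independent, so they do not cover the spread between libraries.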

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

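Most settings below were planned before the data were examined. Mlycd was lower in DBA/2J under every setting and past the threshold under all but those leaving out a DBA/2J library; with each library left out, its log2 difference ranged from -0.96 to -0.85. Without DBA/2J replicate 1 it was -0.89 and without DBA/2J replicate 2 it was -0.94, neither past the threshold. These fits have fewer samples, and the spread then rests on the C57BL/6J pair, which differed more. Without a C57BL/6J library it rests on the DBA/2J pair, which differed less. Without C57BL/6J replicate 2 the lone C57BL/6J library is also the one that stood apart in acute phase genes. Counts of higher and lower genes were 809 and 707 with no low-count filter, where more genes are tested, 421 and 341 at an adjusted p below 0.01 and 459 and 289 against a 1.5-fold change. They ranged from 186 to 2450 higher and from 106 to 2454 lower with each library left out. DESeq2 gave 3300 calls, limma-voom 2752 and the legacy quasi-likelihood fit 2799. Genes called near Mlycd were 1 with RLE scaling, limma-voom or no filter, 0 at an adjusted p below 0.01 or against 1.5-fold, and 0 to 3 with each library left out. Gene lists called were 10 with limma-voom and 11 with no low-count filter or against 1.5-fold, against 9. Camera with an estimated correlation called 0, fry called 0, and fry's test of change in either direction called 29. In camera with an estimated correlation every tested list had the same adjusted p of 0.962, which does not rank the lists. Before adjustment, the camera p of the 9 lists was lowest for endoplasmic reticulum stress (0.0507) and oxidative phosphorylation (0.0554). It was highest for the acute phase list (0.554). Estimated correlations of the 9 lists ran from 0.055 (oxidative phosphorylation) to 0.93 (acute phase), against the preset 0.01. The preset p-values therefore assume far less shared variation than was estimated for some lists. How much of the loss this accounts for was not tested. The share lower in DBA/2J was 54.9% among genes of at least 5 CPM, 44.8% at an adjusted p below 0.01, 34.7% with library totals only, and 36.3% to 51.7% with each library left out. Adjacent called pairs exceeded shuffles under every setting run.

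The replicate numbers do not pair animals by any label, and the differences between replicates 1 and 2 of the 2 strains correlated at -0.064 across genes. With a replicate block 2396 genes were called (1220 higher and 1176 lower), and Mlycd stayed called.

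Of 142 named genes that were called, 59 kept the call with each library left out, 80 lost it without DBA/2J replicate 1 and 81 without DBA/2J replicate 2. Log2 values of genes not called changed sign without C57BL/6J replicate 1 for 4 genes, with these ranges over the 4 libraries left out: Sox9 (-0.76 to 0.0103), S100a9 (-4.04 to 0.22), S100a8 (-3.63 to 0.60) and Mmp9 (-1.62 to 0.56). Depth limited genes at 0 to 3 counts in a strain, such as Tmc5 and Cela2a.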

Other observations

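The test of oxidative phosphorylation genes taken separately was chosen after a related result was seen, and the genes named here were chosen after their values were seen. Processed pseudogenes, the intron-less genomic copies of expressed genes, differed mostly in 1 direction. Their counts with all libraries include copies annotated as transcribed, whereas their counts with a library left out do not. Of 352 tested, 95 were called higher in DBA/2J and 9 lower by edgeR, whereas 1159 protein-coding genes were called higher and 1255 lower. The pseudogene calls were 36 higher and 2 lower without DBA/2J replicate 1, 38 and 2 without DBA/2J replicate 2, and 93 and 18 without C57BL/6J replicate 2. Gm13394, a copy 99.9% identical to Gapdh over the aligned part, had 4759 and 5256 counts in DBA/2J against 15 and 17 in C57BL/6J, while Gapdh itself stood at -0.67 on the log2 scale, a call lost without either DBA/2J library (edgeR adjusted p up to 0.177). Rpsa-ps10 had 2697 and 3296 counts against 15 and 16, and Gm8730, a copy of Rplp0, had 1563 and 1839 against 20 and 13. Mean CPM of Gm13394, Rpsa-ps10 and Gm8730 was higher in DBA/2J by 96.5, 57.4 and 32.5. Gapdh, Rpsa and Rplp0 were lower by 312, 296.5 and 273 CPM, so each of these copies alone does not make up its parent's difference. For others the gain was larger, as for Gm15920 (6.78 CPM, against a loss of 1.61 CPM for Ndufa12).

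A candidate explanation for the pseudogene pattern is that reads of the expressed parent gene of DBA/2J animals, aligned to a C57BL/6J-derived reference, were counted at the copy. Among pseudogenes called with at least a 4-fold difference, 93.6% were higher in DBA/2J (88 of 94, exact 95% interval 86.6% to 97.6%), against 58.0% of protein-coding genes; 36 of 38 were higher without DBA/2J replicate 1 and 38 of 40 without DBA/2J replicate 2. This share restates the observed direction, and transcription of the copies in DBA/2J would give it as well, so it does not decide between them. The 82 of these copies with a tested parent gene had 75 distinct parents. Of these, 41 were called lower and 2 higher (Glo1 and Eno1b, itself a retrotransposed copy), where 1255 of 13184 protein-coding genes were called lower. The protein-coding genes were not matched to the parents for expression, and the share of called genes that were lower rose with expression. Of 11 parents in the ribosomal protein list, of which 69 of 80 were lower, 10 were called lower, and of 64 others 31; both explanations stay open, since the reads and the DBA/2J genome were not used here.

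For the lower ribosomal protein and oxidative phosphorylation genes, technical explanations were set against a difference between the strains. Counting at annotated copies does not account for the lower median of ribosomal protein genes. With the counts of all annotated copies added, their median log2 was -0.539 (bootstrap interval -0.609 to -0.499), against -0.563 without them. Of these summed counts, 7.65% lay at copies in DBA/2J and 3.84% in C57BL/6J, so counts at copies did differ between the strains. The median does not speak for single genes or for copies that are not annotated. Total exon length and GC content left a median residual of -0.5 (-0.552 to -0.454) after a smooth fit over other genes. As fitted, they do not account for most of the difference, although other genes of like exon length had a median of -0.12. Because total exon length is not the length of the expressed transcript, an effect of transcript length itself stays open. Loss of reads that also match a copy was tested in genes without a copy: oxidative phosphorylation genes of that kind had a median of -0.384 (-0.473 to -0.227, 38 genes), which argues against it there. Over both lists the median was -0.386 (-0.468 to -0.227), but with 3 ribosomal protein genes among the 41 it leaves the explanation open for the ribosome, and a biological difference between the strains was not tested further.

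Neighbouring called genes may reflect families or overlapping exons that share reads. With pairs of the same symbol stem or with overlapping exons left out, 501 called pairs remained against a mean of 430.6 in shuffles, a ratio of 1.16 (one-sided permutation p = 7e-05), so such pairs do not account for the whole excess. Shared haplotypes that differ between the strains, which the design includes, are a hypothesis left untested.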
